A study of Homo sapiens with 12 samples.

How the data were processed

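RNA of PC3E and GS689 cells was profiled by RNA-seq (Illumina HiSeq) and by RASL-seq (Illumina MiSeq), with 3 libraries per line and assay. Per the labels' protocols, cells were extracted with Trizol and libraries were made with the Illumina TruSeq Stranded Total RNA kit; the labels give the molecule as polyA RNA, and steps specific to RASL-seq are not given in the sources used here. Per the submitters' processing notes, STAR 2.5.2a and kallisto 0.43.0 were used and the genome build is hg19. The notes give no role or order for the tools.

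The authors deposited 1 table per assay. Per the file headers, the RASL-seq table has 1 column per library, with a pair of whole-number counts in each cell. None of its cells holds a pair of zeros, and between 34 and 60 events are empty in each library except PC3E replicate 1, which has 0 empty events. Every listed event thus has a count in PC3E replicate 1. Empty cells were read as 0. The header does not say which count of a pair is the included form. The share of the first count correlated with the RNA-seq inclusion level over 1640 events (r = 0.87), so the first was taken as inclusion. In 51 of 51 pairs of events where the upstream junction of an exon is the skipping junction of another event, the counts were identical in all 6 libraries, and for the downstream junction this held in 0 of 41. With the counts of each pair exchanged, the former held in 0 of 51, which gives the same order. The inclusion count is therefore that of the upstream junction, and a junction can be counted in several events. The inclusion level is the inclusion count divided by the sum of both, without length correction, since no lengths come with the table.

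Per the file headers, the deposited RNA-seq table holds inclusion and skipping counts of 2 numbered sets of 3 libraries, with an effective length of 101 for skipping and of 102 to 202 for inclusion. The inclusion level was computed from length-corrected counts. A read can count in several events, so table totals are not sequencing depth. Since the header names no line for the sets, splicing, transcript level and assay-by-line tests planned on the RNA-seq libraries were not run. RNA-seq enters the comparison of levels over all libraries, and values per library are given in the closing section. The number of columns of per-sample values left unused was 0.

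Neither table pairs events with gene names. Names were taken by structure: an event was given a gene when chromosome, strand, exon length and both flanking intron lengths matched an annotated exon and its splice sites in exactly 1 gene of GENCODE release 29, which is on another build. No coordinates were converted, and printed positions are those of the files on hg19, counted from 1. In RASL-seq 1934 of 2023 events (95.6%) matched 1 gene, 43 matched several and 46 none; 1930 had a symbol, in 1429 genes. As a check, matching on the opposite strand gave 1 event, on another chromosome 0, and with a shifted intron length 3. In RNA-seq 109246 of 114816 events matched. Coding status and exon sequences come from the same annotation.

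Splicing was tested on the 6 RASL-seq libraries with a quasi-binomial logistic model per event and an F test of the drop in deviance. Dispersions were moderated across events with limma 3.58.1 in R 4.3.3 (squeezeVar, robust, trend on mean count) and held at 1 or above. A count-based quasi-likelihood fit had been planned. The rules set for the work did not admit that tool where a cell holds several values, although the values can be separated into counts. The planned fit was replaced by this model, which had not been planned in any form. The choice was made after the tables were opened and before any model was fitted to the real counts. The planned second count model was left out under the same rule. Events needed a mean of at least 10 counts per library, at least 1 in each library and at least 10 counts of the rarer form. A call is a Benjamini-Hochberg adjusted p under 0.05 and a difference of mean inclusion of at least 5 percentage points. On data simulated for this comparison (1100 events, 200 changed, 5 runs), the model found 17.3% of changes of 1 and 60.6% of changes of 2 on the log2 odds scale, with 3.38% false calls; limma on the log2 ratio found 3.68% and 40.1%, with 1% false calls. With no change simulated, 4.95% of unadjusted p were under 0.05. The simulation gave all events and libraries the same overdispersion, set beforehand and not estimated from the counts. The real libraries were less even, so these rates may not hold for them.

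Totals per gene were tested with limma-voom, planned as the alternative to a count model, on the counts of both forms summed per gene (unnamed events kept apart), scaled by trimmed means of log ratios. Genes needed about 10 counts in the median library's terms in at least 3 libraries and 15 in all. In simulated data for this comparison (1303 genes, 200 changed, 5 runs) 94% of 2-fold changes were found, with 3.98% false calls. Here too all genes and libraries had the same dispersion, so these rates may not hold for the real libraries. Gene lists were tested with Fisher's exact test (splicing) and limma's camera with a preset correlation of 0.01 (levels, lists of at least 5 tested genes).

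The groups, comparisons, thresholds, gene lists, rule for named genes and most alternatives were set before the data were examined, and the splicing model and the structure match were not. The lists hold ESRP and epithelial to mesenchymal transition splice targets, splicing regulators, actin cytoskeleton, vesicle traffic, apoptosis and cell cycle genes, and epithelial, mesenchymal, prostate luminal, neuroendocrine, hepatocyte and haematopoietic markers. For splicing, the text names the 6 largest rises and falls among called events whose lines do not overlap, with the best-counted event of a gene. It adds the 6 called genes with the largest change of the ESRP and transition list, 3 each of 5 other lists, and FGFR2, CD44, CTNND1, ENAH, ARHGEF11, SLK, ESRP1 and ESRP2 where measured. For levels, it names the 6 largest rises and falls, the 4 called genes with the smallest p of each list, and ESRP1, ESRP2, CDH1, VIM, ZEB1, QKI and RBFOX2 where measured. Not every gene that these rules take is printed. Alternatives covered the test, pseudocount, count filter, minimum change, scaling, replicate number and each library left out. Tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Confidence intervals are at 95%.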

Results

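The series compared PC3E and GS689.Li, written GS689 below. Both are human lines derived from the PC3 prostate cancer line, PC3E with epithelial and GS689 with mesenchymal character. Exon splicing was measured by RNA-seq and by RASL-seq, a targeted assay that ligates pairs of probes across splice junctions and counts the products. Each assay had 3 libraries per line, from cells plated in 10 cm dishes and harvested the next day. The RASL-seq table held 2023 exon events on the plus strand, with 848150, 754338 and 911476 counts in PC3E replicates 1 to 3 and 954120, 848241 and 615758 in GS689 replicates 1 to 3. The RNA-seq table held 114816 exon events in 2 unnamed sets of 3 libraries. Its header does not say which set is which line, so differences between the lines come from RASL-seq alone. The labels number the replicates without saying that they came from separate cultures. The p-values then measure the spread between these libraries, which may be technical. PC3E replicate 2 stood farther from replicates 1 and 3 of its line (chi-square per degree of freedom of the inclusion shares 4.79 and 3.52) than those stood from each other (1.9). The 3 pairs of GS689 libraries lay between 1.62 and 1.99.

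The comparison of the lines in RASL-seq asked which exons are spliced differently between an epithelial and a mesenchymal derivative of one cancer line. Exons of SLK, a STE20-like kinase, and of USO1, a golgin that tethers transport vesicles, were included in most PC3E transcripts and skipped in nearly all GS689 transcripts. The 93 nt SLK exon fell from 81.4% ± 2.79 to 3.19% ± 0.273 (SD, n = 3 per line), and the 21 nt USO1 exon from 79.3% ± 1.58 to 2.35% ± 1.15. Exons of UTRN (utrophin), ITGA6 (integrin alpha 6), TCF7L2 (a Wnt pathway transcription factor) and MYO6 (a minus-end-directed myosin) fell, with changes of -47.3, -44.9, -40.5 and -38.3 percentage points. In the other direction, inclusion rose in GS689 in MADD (a Rab3 exchange factor), EPB41L1 (a membrane cytoskeleton protein) and RHBDD2 (a rhomboid family protein).

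Of 1124 events tested, in 873 named genes, 64 events in 55 named genes changed, 24 with higher and 40 with lower inclusion in GS689. The median change among them was 16.7 percentage points, against 2.14 over all tested events, a gap that the rule for a call helps to set. A change here needs an adjusted p under 0.05 in the quasi-binomial model moderated with limma and a difference of at least 5 percentage points. In 63 of the 64 events no PC3E library overlapped a GS689 library. Over all tested events this held for 265 (23.6%), where chance gives 10%. With limma on the log2 ratio of the counts, the test planned as an alternative, 28 events were called at a pseudocount of 0.5, 27 of them among the 64, against 52 at a pseudocount of 5 and 58 with precision weights. With a minimum change of 20 percentage points 25 events remained.

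**Figure D1:**
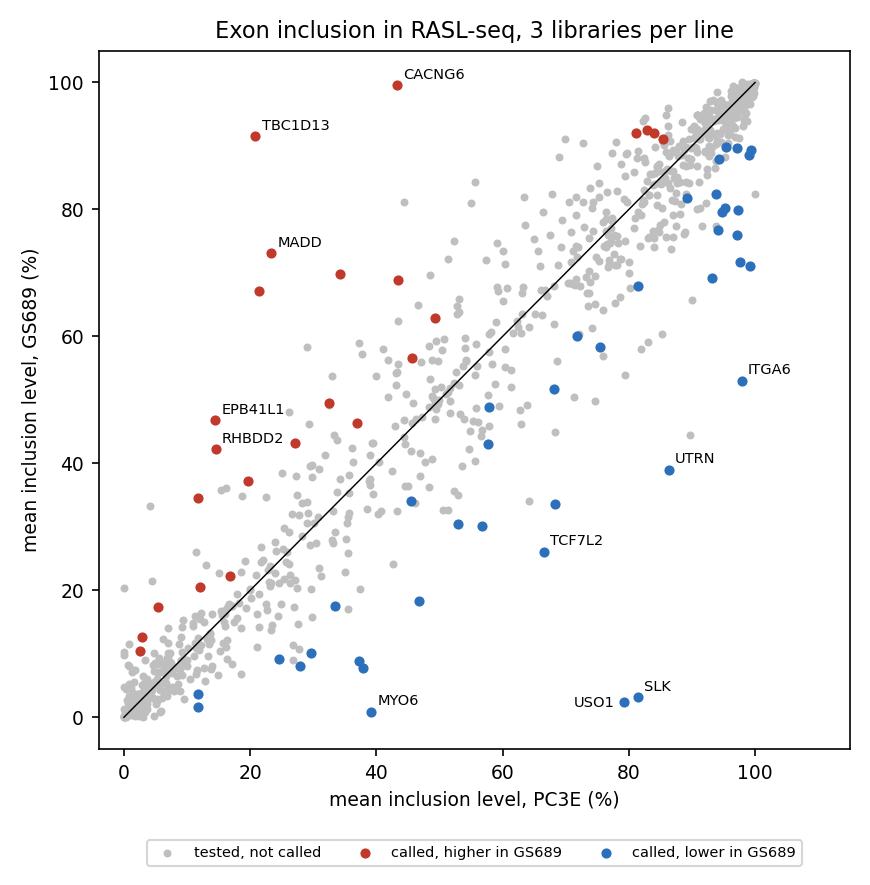
Mean inclusion level of each of the 1124 tested exon events in PC3E (x axis, %) and GS689 (y axis, %), 3 RASL-seq libraries per line, with the line of equal levels. The 24 called events with higher inclusion in GS689 lie above the line and the 40 with lower inclusion below it, with SLK and USO1 at the lower right.

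Of the 64 called events, in 63 distinct exons, 48 were of coding and 9 of partly coding exons. On hg19, the SLK exon lies at chromosome 10, positions 105770574 to 105770666, and the USO1 exon at chromosome 4, positions 76716489 to 76716509; both are coding. Their adjusted p in the limma-moderated model were 5.44e-11 and 7.74e-11. The UTRN exon (chromosome 6, 145148484 to 145148522, 39 nt, coding) went from 86.3% ± 3.08 to 39.0% ± 2.63. The ITGA6 exon (chromosome 2, 173366500 to 173366629, 130 nt, partly coding) went from 97.9% ± 1.11 to 53.0% ± 2.37. In TCF7L2 a 73 nt coding exon (chromosome 10, 114920378 to 114920450) fell from 66.6% ± 6.57 to 26.1% ± 3.52 in the event with more counts, and from 33.5% ± 5.64 to 17.5% ± 6.79 in a second event of the same exon with another upstream splice site. The 27 nt coding exon of MYO6 (chromosome 6, 76621389 to 76621415) fell from 39.2% ± 9.96 to 0.893% ± 1.55 (SD, n = 3 for each of these means). Mean depth per library behind these 6 exons ranged from 147 counts for MYO6 in GS689 to 1655 for SLK in PC3E. The exon sequences, from the annotated transcripts, are GGTGATAAGATCGACAGACGG in USO1, ATTTTGCACCATTTTTGAACAATTCAC in MYO6 and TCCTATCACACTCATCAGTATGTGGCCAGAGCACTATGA in UTRN.

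Among the rising exons, the 60 nt coding exon of MADD (chromosome 11, 47310519 to 47310578) went from 23.3% ± 1.63 to 73.1% ± 14. In EPB41L1 a 36 nt coding exon (chromosome 20, 34783251 to 34783286, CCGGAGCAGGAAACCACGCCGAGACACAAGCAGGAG) rose from 14.5% ± 3.78 to 46.8% ± 3.72. A 122 nt partly coding exon of RHBDD2 (chromosome 7, 75510683 to 75510804) rose from 14.6% ± 6.01 to 42.2% ± 3.94 (SD, n = 3 for each of these means). The largest rises rested on few counts. For MADD the means were 30.0 counts per library in PC3E and 42.0 in GS689. TBC1D13, a Rab GTPase-activating protein, went from 20.8% ± 8.78 to 91.5% ± 3.98 with means of 7.67 and 16.7 counts per library. CACNG6, a calcium channel gamma subunit, went from 43.3% ± 27.4 to 99.6% ± 0.628 with 10.3 and 51.0. Adjusted p over these 5 exons in the limma-moderated model ran from 6.09e-05 for EPB41L1 to 0.00375 for RHBDD2. MYO6 did not pass with precision weights in limma on the log2 ratio (adjusted p 2.39e-06 to 0.11 over all alternatives, that being the highest), and MADD did not without GS689 replicate 3 and PC3E replicate 2 together (0.000174 to 0.0684).

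**Figure D2:**
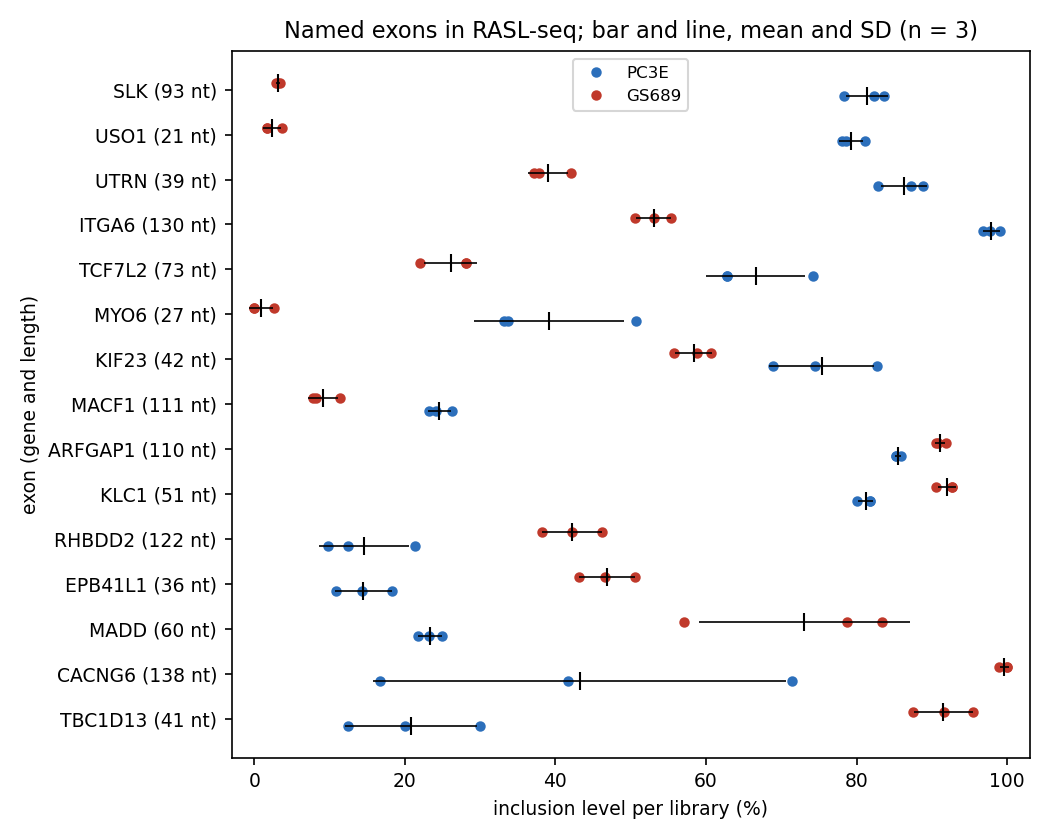
Inclusion level (x axis, %) of the named called exons in each of the 3 PC3E libraries (blue) and 3 GS689 libraries (red); the black bar and line give the mean and SD. The points of the lines do not overlap for any of these exons, and the PC3E points of CACNG6, at about 10.3 counts per library, spread most widely.

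Known targets of the ESRP splicing regulators and exons known to switch in epithelial to mesenchymal transition formed the gene group with the most changes. With 1 event per gene, 15 of its 33 tested genes changed, 11 lower and 4 higher in GS689, against 36 of 840 other genes (4.29%). The odds ratio was 18.6 (Fisher's exact test, 2-sided, adjusted p = 1.45e-10 over the lists). The count was 17 when adjusted over the list alone. With limma on the log2 ratio, 7 of the 33 list genes and 13 of the 840 others were called (odds ratio 17.1, Fisher's exact adjusted p = 2.5e-05). Besides SLK, ITGA6, TCF7L2 and MYO6, members that changed included PTPRF, RALGPS2, TSC2, YAP1, UAP1, NEDD4L and INF2, which fell, and MAP4K4 and NFYA, which rose; those of them that the rule for named genes leaves out were chosen after their values were seen. The list was written from general knowledge, part of which was built on lines such as these, so its count is not independent evidence. The inclusion count is that of the upstream junction of each exon alone.

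Actin cytoskeleton genes had 4 changed among 18 tested, INF2 and MYO6 among them, and all 4 are also in the ESRP and transition list (Fisher's exact adjusted p = 0.0688, odds ratio 4.91, 6 adjusted over the list alone). Limma on the log2 ratio called 1 of the 18 and 1 of 12 vesicle traffic genes. Counting a gene as changed when any of its events was called added MACF1, a microtubule and actin crosslinker. MACF1 is also in the ESRP and transition list, and the Fisher's exact adjusted p was then 0.0151. The MACF1 exon (111 nt) fell from 24.6% ± 1.55 to 9.14% ± 1.95. Vesicle traffic genes had 3 changed of 12 (Fisher's exact adjusted p = 0.0757, 3 adjusted over the list alone). Of these, the kinesin light chain KLC1 rose from 81.2% ± 1.01 to 92.0% ± 1.21, ARFGAP1, a regulator of Golgi coats, rose from 85.4% ± 0.401 to 91.1% ± 0.719, and KIF23, a mitotic kinesin, fell from 75.4% ± 6.97 to 58.4% ± 2.48 (SD, n = 3 for each). ARFGAP1 lost its call without PC3E replicate 3 (adjusted p = 0.0592), GS689 replicate 1 (0.0588) or GS689 replicate 2 (0.0688), and KIF23 without PC3E replicate 3 (0.0511) or GS689 replicate 1 (0.0701). Both also lost it with limma on the log2 ratio, and over all alternatives their adjusted p ran from 0.00774 to 0.161 and from 0.00184 to 0.157. Of 17 splicing regulators and 8 apoptosis genes 0 changed in the limma-moderated model at 1 event per gene, 0 when adjusted over the list alone and 0 with limma on the log2 ratio, while 4 and 1 had an unadjusted p under 0.05 (Fisher's exact adjusted p = 0.823 and 1.0). In the apoptosis list MADD changed at another event. KIF23 was the only one of 8 cell cycle genes to change (1 adjusted over the list alone), and SPINT2 of 2 epithelial markers (1 adjusted over the list alone), with Fisher's exact adjusted p of 0.613 and 0.226. The 1 tested mesenchymal marker did not pass in either limma test, nor at an unadjusted p under 0.05 or adjusted over the list alone. Prostate luminal, neuroendocrine, hepatocyte and haematopoietic markers had 0 tested genes.

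CTNND1, the catenin p120 and a known ESRP target, had 4 tested events and none was called. Its 289 nt partly coding exon at chromosome 11, 57558857 to 57559145, stood at 0.304% ± 0.178 in PC3E and 4.43% ± 0.526 in GS689 (n = 3). The adjusted p in the limma-moderated model was 0.00041, and the difference of 4.13 percentage points was under the minimum of 5. Over all libraries RASL-seq read this exon at 2.37% and RNA-seq at 30.6%, so the missed minimum does not show that the exon is unchanged. The exon at 57556509 went from 0% to 20.4% ± 10.7 without overlap, at means of 4.67 and 27.7 counts per library. At this depth it did not pass (adjusted p = 0.206 in the limma-moderated model). CD44, the hyaluronan receptor, had 2 measured exons and too few counts in GS689 for a test. The coding exon with more counts (chromosome 11, 35229652 to 35229753) had 249 inclusion and 9 skipping counts over the PC3E libraries, and 2 and 0 over the GS689 libraries. FGFR2, ENAH, ARHGEF11, ESRP1 and ESRP2 had 0 events in the RASL-seq table used here.

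Summed over both splice forms, the RASL-seq counts of a gene give a total over its measured junctions, which can differ from the level of the gene where these junctions are themselves alternative. VIM, the mesenchymal intermediate filament vimentin, rose 23.0-fold in GS689, from 185 ± 25.3 to 4259 ± 123 CPM, counts scaled to a common library total (SD, n = 3). The epithelial genes LSR, OCLN, SPINT2 and LLGL2 all had lower totals. In total 391 of 1319 genes or unnamed events changed by limma-voom at an adjusted p under 0.05, 218 higher and 173 lower, 88 and 73 of them by over 2-fold. Without GS689 replicate 1 the count was 254, and with skipping counts alone, which tested 907 genes, it was also 254.

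The 6 largest rises after the fit were in SOBP, FLI1 (an ETS transcription factor), MARK1 (a microtubule affinity kinase), PRR16, VIM and MAP1B (a microtubule-associated protein). The log2 changes were 6.97 for SOBP (SE 0.528; 4.57 with skipping counts alone and 6.23 without PC3E replicate 2), 4.62 for MARK1 (SE 0.437), 4.54 for PRR16 (SE 0.423), 4.52 for VIM (SE 0.139) and 3.96 for MAP1B (SE 0.309). FLI1 had 2 counts over the PC3E libraries and 163 over the GS689 libraries, a ratio of 84.7 with an exact counting interval of 23.1 to 706. The 6 largest falls were in IL1RN (the interleukin 1 receptor antagonist), LSR (a tricellular junction protein), VCAN (the proteoglycan versican), EPS8L1, CD44 and ASS1 (argininosuccinate synthase). IL1RN and EPS8L1 had 0 counts over the GS689 libraries, and 68.1 ± 8.24 and 42.0 ± 33.5 CPM in PC3E (SD, n = 3). They were at least 54.8-fold and 32.7-fold lower in GS689, with a floor of 3 counts over the line. For EPS8L1, counted mostly in PC3E replicate 2, the bound was 18.8-fold without that library, and 19.8-fold and 21.2-fold without GS689 replicates 1 and 2, where the floor rests on fewer libraries. For IL1RN it was 33.2-fold and 35.6-fold without these GS689 replicates. LSR had 233 counts in PC3E and 2 in GS689, a ratio of 112 with an exact counting interval of 30.7 to 931. The total of CD44, from 2 alternative exons, fell 49.4-fold, from 112 ± 21.0 to 1.83 ± 1.23 CPM (SD, n = 3). In RNA-seq another CD44 exon, at 35232793, had 2685 to 2829 counts per library in set 1 and 3378 to 3888 in set 2, so the RASL-seq total is not read as the level of CD44. The LSR change was -6.43 on the log2 scale, and -7.37 without GS689 replicate 3. On the log2 scale VCAN fell by 6.13 (SE 0.845; changes of -5.06 without GS689 replicate 1 and -6.96 without GS689 replicate 3) and ASS1 fell by 5.02 (SE 0.675). Intervals and floors cover counting error only. The adjusted p of these 12 genes in limma-voom ran from 4.09e-09 for VIM to 0.000666 for VCAN.

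**Figure D3:**
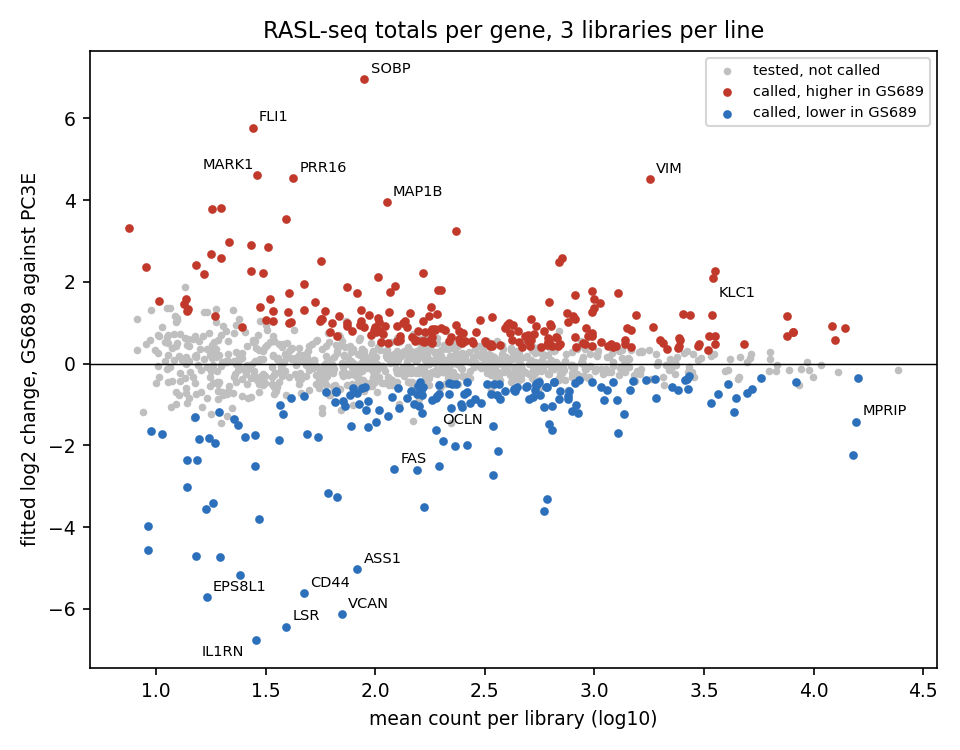
Fitted log2 change of the RASL-seq total of each tested gene or unnamed event, GS689 against PC3E (y axis), against its mean count per library (x axis, log10). The 218 called higher in GS689 are red and the 173 called lower are blue, with VIM standing out among deeply counted genes; fitted changes of genes at 0 counts in a line, such as IL1RN, are not bounds.

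All 4 tested epithelial markers fell, with 4 adjusted over the list alone. LSR is given above. OCLN (occludin) fell by 1.62 on the log2 scale (SE 0.222), LLGL2 (a polarity protein) fell by 1.75 (SE 0.361) and SPINT2 (a serine protease inhibitor) fell by 0.98 (SE 0.184), with a change of -2.0 for skipping counts alone. Of 3 tested mesenchymal markers, VIM rose and 2 did not pass (adjusted over the list alone, 2 of the 3 passed, VIM included). ZEB1, a repressor of epithelial genes, had 1 count over the PC3E libraries and 44 over the GS689 libraries and was too low for the test. ESRP1, ESRP2, CDH1, QKI and RBFOX2 had 0 events in the RASL-seq table used here.

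Of the 6 lists with enough tested genes for limma's camera, apoptosis genes were the 1 list called, with 5 of 11 tested genes lower, 0 higher, and 5 adjusted over the list alone (preset correlation of 0.01, adjusted p = 0.0145). With an estimated correlation the call was lost (adjusted p = 0.34). The death receptor FAS fell 6.02-fold (log2 change -2.59, SE 0.256), the BH3-only protein gene BCL2L11 2.12-fold, the mitochondrial ribosome protein gene DAP3 1.99-fold and BCL2L13 1.82-fold; CASP8, the initiator caspase, fell by 0.82 (SE 0.258) on the log2 scale. BCL2L13 did not pass with skipping counts alone (adjusted p 0.000229 to 0.062 over all alternatives, that being the highest).

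Actin cytoskeleton genes moved both ways, 5 higher and 8 lower of 26 (16 adjusted over the list alone; camera adjusted p = 0.347). LIMCH1 fell 9.87-fold, CYFIP2, a WAVE complex subunit, 9.58-fold and MPRIP, a myosin phosphatase partner, 2.68-fold. Of the 36 tested genes of the ESRP and transition list, 7 were higher and 11 lower (24 adjusted over the list alone; camera adjusted p = 0.347). RAC1 rose by 0.66 on the log2 scale (SE 0.102), and LSR and MPRIP fell. Vesicle traffic genes had 5 higher and 1 lower of 15 (7 adjusted over the list alone; camera adjusted p = 0.466). KLC1 rose 4.26-fold, from 1624 ± 30.7 to 6978 ± 1074 CPM (SD, n = 3), with a log2 change of 2.09 and of 0.86 for skipping counts alone. ARFIP1 rose by 0.93 (SE 0.175) and ITSN1 by 0.53 (SE 0.127), and the endocytic adaptor EPN2 fell by 1.62 (SE 0.144). ITSN1 did not pass with skipping counts alone (adjusted p 0.0076 to 0.699 over all alternatives).

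Of 21 splicing regulators 2 rose and 3 fell (5 adjusted over the list alone; camera adjusted p = 0.466). MBNL1 rose by 0.67 on the log2 scale (SE 0.166) and RALY by 0.49 (SE 0.138), while MBNL2 fell by 0.68 (SE 0.151) and MATR3 by 0.67 (SE 0.166). The call of MBNL1 was lost without GS689 replicate 1 (adjusted p = 0.0532), that of MATR3 without GS689 replicate 1 (0.0518) or with skipping counts alone (0.601), and that of RALY without GS689 replicate 3 (0.0722). The lowest adjusted p over the alternatives were 0.00477, 0.00759 and 0.0094 for MBNL1, MATR3 and RALY. Of 8 cell cycle genes the retinoblastoma gene RB1 rose by 0.94 (SE 0.184) and CDK10 fell by 0.84 (SE 0.261), with 2 adjusted over the list alone and a camera adjusted p of 0.6. CDK10 lost its call without PC3E replicate 3 (adjusted p = 0.05), GS689 replicate 1 (0.132), GS689 replicate 2 (0.059) or GS689 replicate 3 (0.106), and its lowest over the alternatives was 0.00149. With an estimated correlation no list was called. Prostate luminal, neuroendocrine, hepatocyte and haematopoietic markers had 0 measured genes here as well.

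The last comparison set the inclusion levels of the same exons in both assays side by side, over all libraries of both lines. As means of the 6 libraries of each assay, the SLK exon stood at 42.3% in RASL-seq and 31.7% in RNA-seq. In CTNND1 the 63 nt exon at 57581783 stood at 97.6% and 96.2%, and the 289 nt exon at 57558857 at 2.37% and 30.6%. With RASL-seq counts summed over libraries instead, which weights deeper libraries more, SLK stood at 54.1% and the 289 nt exon at 1.29% in RASL-seq, and the values over all exons use these sums unless stated. Over 1640 exons with a mean of at least 10 counts per library in both assays, Pearson's r was 0.87 and Spearman's rank correlation 0.871 (permutation p = 1e-05 for both, the smallest that 100000 resamples can give, and 1e-05 after adjustment over these 2 correlations). The correlation is across exons, which are not independent replicates. Its sign was used to tell which count of a pair is inclusion, so the p-values do not test the sign. The median absolute difference was 4.76 percentage points, and 64.6% of exons lay within 10 points. In 88 exons the assays differed by over 50 points, RASL-seq being higher in 32 and lower in 56. With means of libraries in both assays, r was 0.871, the median difference 4.69 points, and the number of exons over 50 points apart 88.

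**Figure D4:**
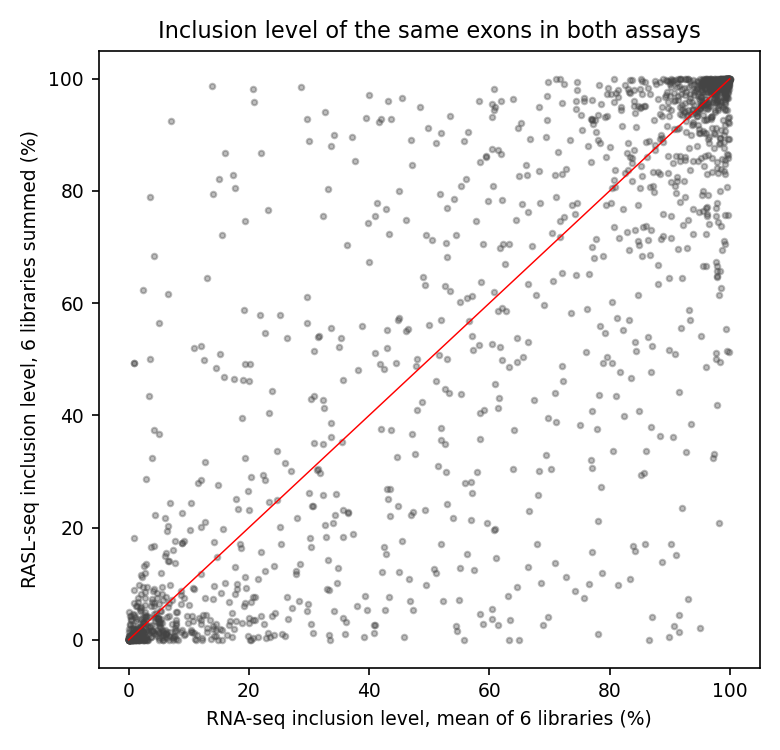
Inclusion level of 1640 exons in RNA-seq (x axis, %, mean of the 6 libraries) and RASL-seq (y axis, %, counts of the 6 libraries summed), with the line of equal levels in red. Most exons lie near the line, while 88 lie over 50 percentage points from it.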

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

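The measure of spread and the count limit used for these exons were chosen only after their levels were seen, while the test of the signs in the last paragraph was set before its result. The following exons have levels in RNA-seq data that no comparison between lines above uses, with more than 3 counts in each set of libraries. The sets lie apart by more than the intervals of single libraries for ARHGEF11, CD44 and ENAH, and not for ESRP1 and ESRP2. For each gene the event whose rarer form has most counts was taken, and values are inclusion levels per library with the spread between the highest and lowest of the 6 libraries. Wilson intervals of single libraries, for counting error only, are at most 7.28 percentage points wide for CD44, ENAH and ARHGEF11.

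The 96 nt coding exon of ARHGEF11 at chromosome 1, 156908210 to 156908305, had a spread of 90.6 percentage points. It stood at 2.52%, 1.59% and 1.67% in set 1 and at 90.9%, 92.2% and 89.8% in set 2. A 204 nt coding exon of CD44 (chromosome 11, 35232793 to 35232996) had a spread of 72.2 points, with 74.9%, 70.5% and 73.3% in set 1 and 2.7%, 2.8% and 3.34% in set 2. The 63 nt coding exon of ENAH, an actin regulator (chromosome 1, 225692693 to 225692755), had a spread of 63.4 points, with 57.4%, 65.0% and 64.0% in set 1 and 2.21%, 1.56% and 2.88% in set 2. A 151 nt coding exon of ESRP1 (chromosome 8, 95704905 to 95705055) had a spread of 32.1 points, from 67.9%, 70.7% and 72.0% in set 1 to full inclusion in 3 and 2 counts of 2 libraries of set 2, the other having 0 counts. At this depth no difference can be read for ESRP1. A 133 nt coding exon of ESRP2 (chromosome 16, 68266274 to 68266406) had a spread of 11.2 points, with 96.0%, 97.4% and 94.6% in set 1 and 86.2%, 90.3% and 95.4% in set 2; the sets overlap and intervals are up to 14 points wide, so no difference can be read for ESRP2 either. FGFR2 had at most 3 counts in any library. No biological explanation was tested for these exons.

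The header does not tie the sets to the lines, and the values above take part in no comparison of lines. Of the 64 events called in RASL-seq, 63 (98.4%, exact interval 91.6% to 99.96%) had a difference of set 2 minus set 1 with the sign of GS689 minus PC3E, and 1.56% the opposite sign; the exception was FOXRED1. Among 1054 tested events without a call 65.7% had the same sign, and over all 1118 the changes correlated (r = 0.664, permutation p = 1e-05, the smallest possible; across events, which are not replicates). These signs argue against set 1 being GS689. If each set holds the libraries of 1 line, set 1 is then PC3E and set 2 GS689. This assignment rests on the values and not on a label.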

How the results depend on the processing

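The tests with precision weights, Pearson dispersion, the shallowest libraries left out, events with empty cells left out, a mean of at least 100 counts, 1 event per gene, rank correlation, raw count share, means of libraries in RASL-seq and list tests on limma calls were chosen after seeing the data. Among named genes, 316 values of inclusion changes under the alternatives and 403 of totals kept direction and side of the threshold, 18 and 10 lost their call, 1 gained one (CTNND1 without a minimum change) and 0 reversed. The 64 splicing calls became 28 with limma on the log2 ratio at a pseudocount of 0.5, 52 in the same test at a pseudocount of 5 and 58 with precision weights, so that count depends on the pseudocount and the weights (the cause of the remaining difference was not tested), and 25 with a minimum change of 20 percentage points, by construction. The remaining settings, apart from the replicate block, gave 46 to 83, and leaving out each library 44 to 81 (lowest without GS689 replicate 3, highest without PC3E replicate 2); 0 shared calls changed direction in any of them. The 391 changed totals became 254 with skipping counts alone, where fewer genes are tested, and 3 of the 214 shared calls changed direction. Leaving out each library gave 254 to 449 (lowest without GS689 replicate 1, highest without PC3E replicate 2; the cause was not tested), and the remaining settings, again apart from the block, 290 to 404, with 385 for 1 event per gene. Pairing by replicate number was not clear, since not every library correlated best with its own number. Deviations of same-numbered libraries correlated at 0.037, 0.004 and 0.034 for splicing and at 0.264, 0.162 and -0.02 for totals. For totals, PC3E replicates 1 and 2 did correlate best with their own number, so a shared batch is not excluded. With a replicate block 88 events, 465 totals and 1 gene list were called. The correlation of the assays ran from 0.858 to 0.925 over all settings (0.867 to 0.871 leaving out each library). Lists called for splicing rose from 1 to 2 when any event of a gene counted and numbered 1 with limma calls. Lists called for totals went from 1 to 0 with an estimated correlation and 4 with fry, which asks another question. Not run were the planned count-model alternatives, all alternatives on RNA-seq tests and the assay difference, whose sets have no named line, a call size for RNA-seq, and a length correction in RASL-seq, which has no lengths. Depth limits what can be read from thinly counted exons: events with about 10 counts per library in a line, such as TBC1D13 and, in PC3E, CACNG6, have wide counting error.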

Other observations

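The tests of the ESRP and transition list and of genes changed both in splicing and in total were chosen after the calls were seen; so were those on distinct exons, while those of reading frame, exon length, listing and splits were set before. Genes named only in the next paragraph were chosen after their values were seen.

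In 5 genes more than 1 event changed. TCF7L2 had 3 called events, with changes in GS689 of -40.5 and -16.0 percentage points in 2 events of the same exon and of -28.4 in another exon, and PTPRF, a receptor tyrosine phosphatase, had 2, with -30.3 and -28.1. INF2, a formin, and UAP1 had 2 each, all lower; those of UAP1 are versions of 1 exon. EPB41, a membrane cytoskeleton protein, had 2 events that went apart, a 63 nt coding exon from 97.2% ± 0.523 to 89.7% ± 3.55 and a 42 nt coding exon from 2.93% ± 1.38 to 12.6% ± 0.979 (SD, n = 3). In YAP1, the Hippo pathway coactivator, a 48 nt coding exon fell from 56.7% ± 1.53 to 30.2% ± 1.94. In ERBIN, a scaffold at the basolateral membrane, a 144 nt coding exon rose from 11.7% ± 2.75 to 34.6% ± 5.26. A 60 nt coding exon of TERF1, a telomere repeat binding factor, fell from 52.9% ± 2.58 to 30.5% ± 2.21 at means of 1446 and 1155 counts per library. A 129 nt coding exon of TSC2, tuberin, fell from 93.2% ± 3.63 to 69.3% ± 11.6.

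In the RNA-seq table the summed counts of ESRP1 were 282, 371 and 339 CPM (of the table total) in set 1 and 0.149, 0.947 and 0.544 in set 2. ESRP2 had 88.7, 67.6 and 94.3 in set 1 and 14.1, 14.8 and 13.5 in set 2, and CDH1 (E-cadherin) 107, 88.4 and 112 in set 1 and 0.597, 1.34 and 0.638 in set 2. VIM had at most 64.4 in set 1 and 1380, 1280 and 1460 in set 2. ZEB1 had 0.156, 0.0 and 0.182 in set 1 and 2.14, 1.26 and 1.01 in set 2. QKI lay between 48.3 and 70.6 and RBFOX2 between 36.5 and 57.4 in the 6 libraries. The CTNND1 exon at 57558857, with 4.43% inclusion in GS689 by RASL-seq, stood at 6.25%, 6.78% and 5.02% in set 1 and at 58.7%, 53.5% and 53.6% in set 2 (Wilson intervals at most 9.18 points wide). The header names no line for the sets. If each set holds the libraries of 1 line, the signs of the called events given above make set 1 PC3E and set 2 GS689. VIM went the same way in the RASL-seq totals, from 185 CPM in PC3E to 4259 CPM in GS689. On that reading ESRP1, ESRP2 and CDH1 were lower in GS689 and the CTNND1 exon was included more often there. No test between the lines was run on these RNA-seq values.

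Genes of the ESRP and transition list changed their splicing more often than others. A technical explanation is that they are counted more deeply. Of 10000 random lists matched on counts, 0 held as many as the 15 changed genes of the list, with a median of 1 and a highest count of 7, which argues against depth. Counting the list itself the share is 0.01%, the smallest that this many lists can give. A change in total counts of the same genes is another. Among genes whose total was not called, 9 of 18 list genes and 21 of 582 others had a changed exon (odds ratio 26.7, Fisher's exact p = 1.98e-08), which argues against it. A candidate explanation is a difference in ESRP activity between the lines, which no test here addresses, and choice of the list from studies of like cells stays open. The random lists were matched on counts only and not on inclusion level. Whether exons of the list were less often near full inclusion or full skipping than other tested exons was not tested.

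The table lists only events with a count in PC3E replicate 1, which could add falls in GS689 and hide genes silent in PC3E. Of all changed totals 44.2% were lower in GS689, and of the 290 changed among genes with a mean of at least 100 counts it was 43.8%. The scaling centres the changes in both (median log2 change -0.005 and -0.012) and the sets share 278 calls, so the shares decide nothing and the explanation stays open. Genes without a count in PC3E replicate 1 are not analysed here, so rises from 0 stay open.

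The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 64 exon events and 391 totals, 1 split of 10 in both cases, and the highest other split gave 0 and 0. Every other split mixes libraries of both lines, so line differences enter the spread within its groups and can lower the calls. The counts of 0 therefore do not measure how many calls arise without a line difference.

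It was asked whether exons that changed may keep the reading frame. Of 48 changed events of coding exons 37 (77.1%) had a length divisible by 3, against 486 of 745 other events (65.2%), which leaves the question open (Fisher's exact p = 0.116, odds ratio 1.79). Counting each exon once, 37 of 47 (78.7%) and 476 of 731 (65.1%) did (p = 0.0581, odds ratio 1.98, Fisher's exact test). Exons of changed events were shorter than those of other tested events, with a median of 71 nt against 99 nt (permutation p = 0.00042; 0.00018 counting each exon once), consistent with the hypothesis set beforehand. Genes with a changed exon may also change in total more often: 21 of 51 (41.2%) did, against 248 of 818 (30.3%), which the test leaves open (Fisher's exact p = 0.118).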
